A study of Homo sapiens with 6 samples.

How the data were processed

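Total RNA from 6 untreated lung adenocarcinoma cell lines grown in RPMI-1640 medium was turned into biotin-labelled cRNA from an oligo(dT) primer and hybridised to oligonucleotide arrays with 54675 probe sets, per the labels' protocols. Each line has 1 array, the submitters state that there were no replicates, and the original scanner files were lost, per the series' design text. The deposited intensity values are MAS5 signals on a linear scale, per the submitters' processing notes and the file headers, and the version of the software is not given in the sources used here. A trimmed mean near 100 on all 6 arrays shows that the authors had scaled the deposited intensities to a common level. No detection calls were used here. The 2 deposited tables held the same values in 100% of cells. Gene symbols, Entrez identifiers, cytobands and alignments to the human assembly NCBI Build 36.1 are those of the deposited table, and positions are printed as given there.

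Of the 54675 probe sets, 62 were controls, 8421 had no gene symbol, 1219 had several and 44973 had 1. Only the last group was named. Their symbols were updated through the Entrez identifier with a RefSeq gene table of assembly GRCh38.p14, which was used only for names and for excluding chromosome Y, and 43299 were matched and 1674 kept the name in the file. Signals were scaled to a 2% trimmed mean of 500, a factor of 5 on each array, and compared as log2(signal + 32), a pseudocount of 6.4 in deposited units, which understates differences of genes with low signal. The probe set with the highest mean log2 value stood for its gene (19674 genes), and a gene entered if its scaled signal reached 200, or 40 in deposited units, on at least 1 array (12769 genes). The precision of the values is limited by the number of arrays.

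Each line was compared with the other 5. A gene was counted as set apart when it lay at least 4-fold above the highest or below the lowest of the other 5 lines. With 1 array per line there is no test between lines and no p-value across genes. The differences carry the SD of the other 5 lines, which measures how those lines differ and not the error of a measurement. The SD between probe sets of the same gene was the only repeated measurement within an array. For each of 28 gene lists (473 genes, 348 of them measured) the median difference of the measured members was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, and a list stood apart in the lowest or highest 0.5%. This describes these arrays and is not a test of the lines. Lists with fewer than 5 measured members were not placed, and members were counted as above or below at 2-fold from the mean of the other 5 lines. Genes named in the text are the 10 genes above and the 6 below with the largest gaps per line, or all where fewer, and measured members of the lists, with preference to those with the largest absolute differences. Genes of chromosome Y, XIST and TSIX were excluded from naming, as were uncharacterised loci and open reading frames outside the lists. Some genes that this rule names, and 1 control transcript, are not reported here. Where the other probe sets of a gene named for its difference from the other lines pointed the opposite way, or had a median under 60% of its difference, this is stated. The thresholds, lists, relations and rule for names were fixed before the data were examined.

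Similarity of lines was the Pearson correlation across genes for each of 15 pairs. For 4 relations between mean list levels over the 6 lines, Pearson's r and Spearman's rho were given with two-sided exact permutation p-values over all pairings and Benjamini-Hochberg adjustment over the 4 relations, and r was repeated without the 2 lines farthest from the median of the first measure. Measures of all lists and arrays were screened for a single line far from the other 5 with Dixon's ratio at the 95% level, which chance meets in about 1 of 20 groups. Alternatives were a smaller and a larger pseudocount, no filter on low signal or a minimum of 500, quantile normalization, scaling to the 75th percentile, the median over the probe sets of a gene, only probe sets without the suffixes that mark probes shared between transcripts, a 4-fold distance from the median of the other lines, and leaving out each line in turn. Comparing a line only with the 2 others of the same spike-in brightness, and taking the relations on values less the mean of their array set, were added after the controls were seen.

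Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The search for genes set apart was tested on simulated data made for A549 against the other lines (12769 genes, noise SD 0.6 on the log2 scale). It recovered 32% of 50 genes changed 4-fold, 72% of 50 at 8-fold, 98% of 50 at 16-fold and 100% of 50 at 32-fold, with 4 false calls among 12569 unchanged genes. The simulated lines shared 1 mean per gene, and changes were placed only in genes of middle expression. These rates therefore do not carry over to lines that differ among themselves. Nor do they carry over to noisier arrays, such as NCI-H2228 and NCI-H2009, where the SD between probe sets was 0.893 and 0.759. Of 200 simulated lists without a shift, 2 stood apart, and a list of 15 genes shifted by 1 log2 unit lay at percentile 100.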

Results

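Messenger RNA was measured in 6 human lung adenocarcinoma cell lines, A549, NCI-H2009, LC-2/ad, HCC4006, NCI-H441 and NCI-H2228, all grown without treatment. Each line forms a group of its own with 1 array, so none of the differences reported here has a replicate check. The array covered 54675 probe sets, of which 44973 carried 1 gene symbol, and 12769 genes reached the minimum signal on at least 1 array. Values are MAS5 signals as deposited, and the 2% trimmed mean of every array was close to 100. The share of probe sets at a signal of 40 or more ran from 33.1% in NCI-H2009 to 37.8% in HCC4006. The design asks how the lines differ from one another, and each line was set against the other 5 in turn. Differences are given on the log2(signal + pseudocount) scale as the line minus the mean of the other 5 lines, ± the SD of those 5 lines (n = 5). Where signals of a line or of the others lie under the minimum of 40, the size, the rank and the SD of a difference depend on the pseudocount and are not exact.

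In all, 487 genes (3.81% of those compared) lay at least 4-fold above the highest of the other 5 lines in 1 line, and 584 (4.57%) lay at least 4-fold below the lowest. A549 had 167 such genes above and 162 below, and NCI-H2009 had 83 above and 279 below. The low counts depended on the processing, with 101 in NCI-H2009 and 91 in A549 for the median over probe sets and 103 and 73 with a larger pseudocount. HCC4006 had 113 above and 10 below. NCI-H2228 had 78 above and 38 below, but 47 above and 55 below for the median over probe sets. NCI-H441 had 21 above and 83 below, and LC-2/ad had only 25 above and 12 below. Genes below numbered 35, 11 and 3 in NCI-H441, LC-2/ad and HCC4006 for the median over probe sets. With a larger pseudocount they numbered 28, 1 and 6, and with a smaller one 161, 33 and 17. Of 138 combinations of a gene list with a line, 59 fell within the lowest or highest 0.5% of 10000 random lists of the same size and expression. By chance 1.38 would be met if all combinations were independent, which they are not. The differences of a gene cancel out over the 6 lines by construction, so a list high in 1 line is pushed lower in others. The random lists also do not keep any shared regulation of list members. Of the 59, 30 were higher and 29 lower than in the other lines. Epithelial and NRF2 target genes stood apart in 6 lines, alveolar markers in 5, and cell cycle, secretory and MHC class II genes in 4.

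**Figure D1:**
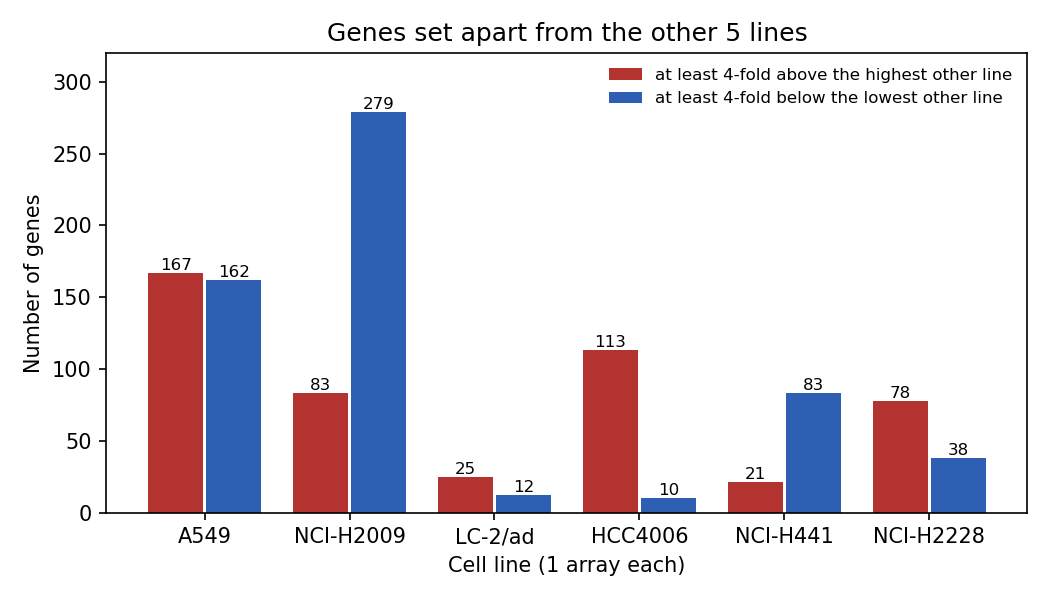
Number of genes (vertical axis) at least 4-fold above the highest (red bars) or below the lowest (blue bars) of the other 5 lines, for each cell line with 1 array. The blue bar of NCI-H2009, at 279 genes, is the tallest, and LC-2/ad has 25 and 12 genes.

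The control probe sets divided the arrays in 2 ways that no label describes. The spike-in transcript cre had a signal of 13226 to 18887 on the A549, NCI-H2009 and LC-2/ad arrays and of 5282 to 5827 on the HCC4006, NCI-H441 and NCI-H2228 arrays, a mean ratio of 2.88, and bioC and bioD differed by mean ratios of 2.22 and 3.13. The 5' probe set of 18S ribosomal RNA differed more, with 328 to 1272 on the former arrays and 33.6 to 67.8 on the latter. These are called the brighter and the dimmer array set, with 3 lines each. The brighter set holds the first 3 samples of the series and the dimmer set the last 3. Across all genes the median of the brighter minus the dimmer set was -0.02 on the log2 scale, and among the 1% of genes with the highest mean signal it was 0.85. Separately, the ratio of 3' to 5' probe set signal on the NCI-H2228 array was 2.46 for ACTB (1.06 to 1.27 on the other arrays) and 1.25 for GAPDH (0.907 to 1.02). Between probe sets of the same gene, the difference from the other lines had an SD of 0.893 in NCI-H2228, 0.759 in NCI-H2009, 0.599 in A549, 0.502 in HCC4006, 0.494 in NCI-H441 and 0.489 in LC-2/ad, over 6289 genes.

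**Figure D2:**
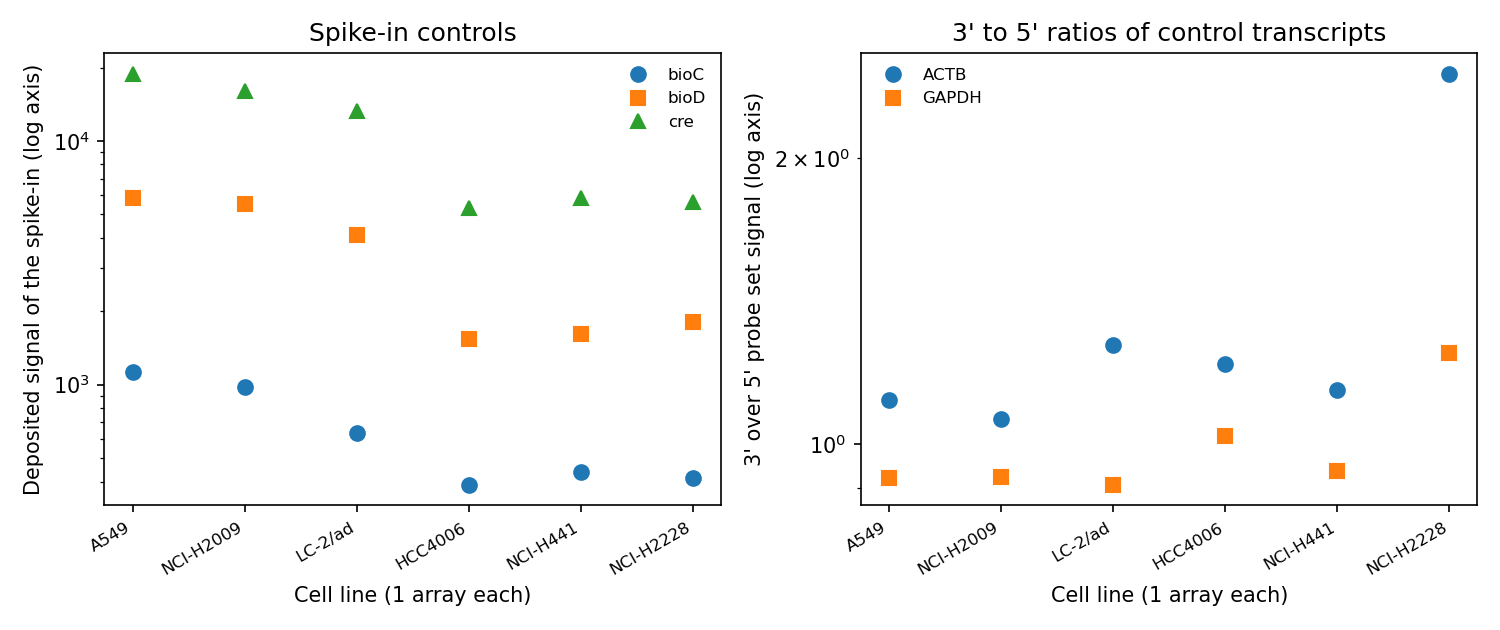
Left, deposited signal of the spike-in controls bioC, bioD and cre on each array (log axis); right, 3' over 5' signal ratio of ACTB and GAPDH probe sets on each array (log axis), 1 point per array. The cre points lie between 13226 and 18887 on 3 arrays and between 5282 and 5827 on the other 3, and NCI-H2228 has the highest ratio of both transcripts.

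A549 had very high signals of several secreted and liver-type protein genes and low signals of many, though not all, epithelial genes. NTS, which encodes the neurotensin precursor (chromosome 12, 84792202 to 84800470 on Build 36.1), had a signal of 12456 in A549 and 1.1 to 7.1 in the other lines, a difference of 10.35 ± 0.36. The aldehyde dehydrogenase gene ALDH1A1 (chromosome 9, 74705406 to 74757791) had 12044 against 0.3 to 10.4, a difference of 9.96 ± 0.50. The tetraspan-family gene TM4SF4, the urea cycle gene CPS1 and the hair keratin gene KRT81 followed at 9.47 ± 0.12, 8.37 ± 0.53 and 7.86 ± 0.52, sizes set partly by the pseudocount because the other lines were near background. At the other end, the mucin gene MUC1 had a signal of 5.8 against 751 to 3320. Its difference was -7.00, with a median of -3.93 in its 2 other probe sets. The peroxiredoxin gene PRDX2 was lower by a difference of -7.90 ± 0.87 and the protease inhibitor gene SPINT1 by -6.37 ± 0.57, but their other probe sets gave far smaller medians of -1.95 and -1.12. The keratin gene KRT19 had 2.0 against 1576 to 9535, although the file aligns its probe set to chromosome 6, away from the gene's own cytoband. IFITM3 had 5.3 against 1366 to 3600, and its sequence is close to those of IFITM1 and IFITM2, so the value is uncertain between them.

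NRF2 target genes, which serve redox defence and NADPH supply, were higher in A549, a line known for an altered KEAP1. Of 26 measured, 22 were at least 2-fold above the mean of the other lines and 0 below, with a median difference of 2.11. The glutathione peroxidase gene GPX2 differed by 6.61 ± 1.97, the aldo-keto reductase gene AKR1B10 by 6.44 ± 2.53 and the transporter gene ABCC2 by 5.77 ± 2.72. The file aligns the AKR1B10 probe set to chromosome 10, away from the gene's cytoband, and the other probe set of GPX2 gave 2.97. Hepatic secreted protein genes had a median difference of 5.91, with 5 of 7 above and 1 below. FGA, FGB and FGG, the fibrinogen chain genes, differed by 7.75 ± 0.27, 6.68 ± 0.34 and 7.71 ± 0.76 and APOH by 5.91 ± 0.72, while the protease inhibitor gene SERPINA1 was lower by a difference of -4.05 ± 0.73 in a probe set that the file aligns to chromosome 15, away from the gene's cytoband. Other probe sets of FGA gave a median of 3.54. Gastrointestinal and mucinous markers had a median of 1.53 (6 of 12 above, 1 below), with CDH17 at 5.39 ± 0.34 and MUC13 at 4.43 ± 1.15. Xenobiotic and aldehyde metabolism had a median of 1.01 (8 of 16 above, 4 below), with the vitamin D hydroxylase gene CYP24A1 at 5.59 ± 1.78. Cell cycle genes had a median of 0.68 (7 of 22 above, 0 below), with the replication clamp gene PCNA at 1.79 ± 0.72.

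Epithelial adhesion and identity genes were lower in A549, with a median of -4.30 and 14 of 20 measured genes below and 2 above. RAB25, CLDN4 and the splicing regulator gene ESRP1 differed by -6.27 ± 2.30, -4.81 ± 0.91 and -4.42 ± 1.02. The keratin genes KRT8 and KRT18 were the 2 above, at 2.51 ± 0.85 (in a probe set that the file aligns to chromosome 1, away from the gene's cytoband) and 1.55 ± 0.68, and the E-cadherin gene CDH1 had a signal of 2056, within the 342 to 4488 of the other lines. Alveolar type II markers had a median of -3.02 (0 of 11 above, 7 below). NKX2-1, the lung lineage transcription factor gene, had a signal of 0.8 against 91.4 to 1227, and SFTA3 had 0.9 against 34.2 to 1702. Secretory airway markers had a median of -3.66 (1 of 7 above, 5 below), with WFDC2 at -4.24 ± 1.18. MAPK pathway feedback and output genes had a median of -1.56 (1 of 18 above, 12 below), with EGR1 at -5.88 ± 1.27 and the ERK phosphatase gene DUSP6 at -4.28 ± 0.69, and DUSP4 as the gene above at 1.76 ± 1.58. Interferon-stimulated genes (1 of 20 above, 14 below), MHC class I presentation (0 of 13 above, 10 below) and MHC class II presentation (0 of 9 above, 7 below) had medians of -1.80, -2.28 and -2.99. In these lists ISG15 differed by -4.70 ± 1.59, the immunoproteasome gene PSMB8 by -3.83 ± 0.74 and the invariant chain gene CD74 by -5.48 ± 2.53, while OAS1 was higher at 2.37 ± 1.12. Smaller differences were read in other probe sets of EGR1 (-2.64), CD74 (-2.05) and OAS1 (1.25). SMARCA4, a chromatin remodeller gene altered in this line, had a signal of 37.3 against 466 to 1511.

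Against the 2 other lines of the brighter array set alone, the A549 medians were 2.24 for NRF2 targets, 6.49 hepatic, 2.06 gastrointestinal, 1.28 xenobiotic, -4.93 epithelial, -1.70 alveolar, -3.13 secretory, -0.99 MAPK output, -1.26 interferon, -3.02 MHC class I and -2.10 MHC class II, but -0.009 for cell cycle genes. The cell cycle median no longer stood apart without HCC4006 (0.38), without NCI-H2228 (0.51) or with the median over probe sets (0.54), nor the gastrointestinal median without NCI-H2009 (0.98) or at a minimum signal of 500 (0.98), nor, with no filter on low signal, the hepatic (0.32), xenobiotic (0.47) and secretory (-0.01) medians, the last also not without shared probe sets (-0.81).

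NCI-H2009 differed from the other lines by a group of genes with low signal, whose number rested on the choice of probe set and pseudocount, and by high signals of CDKN2A and MHC class I genes. The neurofilament gene NEFH (chromosome 22, 28206251 to 28217379) had a signal of 821 in NCI-H2009 and 1.0 to 5.7 elsewhere, a difference of 6.51 ± 0.32. The reductase gene DHRS2 differed by 5.93 ± 0.72 and the meiotic cohesin gene STAG3 by 4.77 ± 0.50. PCDHB5 and PCDHB6, protocadherins of a family with similar sequences, differed by 5.06 ± 0.72 and 4.73 ± 0.35. Of the low genes, GALNT14, a glycosyltransferase gene (chromosome 2, 30986837 to 31214517), had a signal of 1.5 against 286 to 497, and the calcium-binding protein gene S100P had 40.2 against 793 to 5966. The small GTPase gene RAB27B, the forkhead gene FOXQ1, the chromatin gene CHD9 and the DNA polymerase gene POLK differed by -5.25 ± 0.92, -4.80 ± 0.56, -4.53 ± 0.52 and -4.53 ± 0.87, although the median in the other probe sets of RAB27B was -1.30.

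Epithelial adhesion and identity genes were higher in NCI-H2009, with a median of 1.61 and 15 of 20 measured genes at least 2-fold above and 0 below. Their mean log2 level was 12.6 in NCI-H2009, 12.4 in NCI-H441, 12.3 in LC-2/ad and 11.9 in HCC4006. It was 8.4 in A549 and 10.1 in NCI-H2228, so the difference came mainly from those lines in the reference. NRF2 target genes were lower, with a median of -1.14 (2 of 26 above, 14 below). OVOL1 and CDH1 differed by 2.64 ± 1.16 and 1.55 ± 1.22, and the cystine transporter gene SLC7A11 by -5.03 ± 1.32. MHC class I presentation had a median of 1.71 (8 of 13 above, 0 below), with the transactivator gene NLRC5 at 3.19 ± 1.44 and PSMB8 at 2.28 ± 1.59. Cell cycle genes had a median of 1.03 (11 of 22 above, 2 below), with AURKB at 2.94 ± 1.69 and CDC20 at 2.24 ± 0.99. The tumour suppressor list had a median of 1.01 at percentile 99.55 (7 of 14 above, 2 below). Its members included CDKN2A, which encodes the inhibitor p16, with a signal of 4811 against 9.2 to 538, MTAP at 2.97 ± 1.62, and RB1 with a signal of 0.3 against 43.0 to 270.2, whose other probe set differed by -0.95. Cholesterol biosynthesis had a median of 1.05 and a mean of 0.51 (9 of 17 above, 2 below), with FDPS at 1.75 ± 0.35. Alveolar (-1.42), secretory (-1.94), gastrointestinal (-1.32) and hepatic (-1.77) medians were lower, and SLPI, AGR2 and CEBPA from these lists differed by -4.42 ± 0.66, -4.18 ± 0.88 and -2.75 ± 1.0.

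Against the 2 other lines of the brighter set alone, the NCI-H2009 medians were 2.42 epithelial, -1.25 NRF2, 2.01 MHC class I, 1.54 tumour suppressors, -2.02 gastrointestinal and -3.83 hepatic, but 0.25 cell cycle, 0.77 cholesterol, -0.14 secretory and, with the opposite sign, 0.56 alveolar. Epithelial and NRF2 shifts stood apart under every alternative run, the epithelial median at 0.96 without A549, whereas leaving out 1 line ended the calls of the gastrointestinal (-1.03 without A549), hepatic (-0.74 without A549), cholesterol (0.87 without A549, 0.86 without NCI-H2228), tumour suppressor (0.96 without LC-2/ad, 0.86 without HCC4006), alveolar (-0.92 without HCC4006, -0.82 without NCI-H2228), secretory (-0.65 without HCC4006, -1.57 without NCI-H2228) and cell cycle lists (0.75 without HCC4006). Over the alternatives fixed beforehand, the calls ended under 9 of 13 for tumour suppressors, 6 of 13 for cholesterol, 4 of 13 for alveolar and secretory, 4 of 12 for hepatic, 3 of 13 for gastrointestinal, 2 of 13 for cell cycle and 1 of 13 for MHC class I genes (0.92 without shared probe sets). With no filter on low signal the hepatic median had the opposite sign, at 0.23.

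LC-2/ad had the fewest genes set apart. GABRP, a GABA receptor subunit gene (chromosome 5, 170143342 to 170173626), had a signal of 299 in LC-2/ad and 0.3 to 4.5 in the other lines, a difference of 5.26 ± 0.31. The kallikrein gene KLK6 had 1862 against 11.1 to 83.4 (5.84 ± 1.02), and the matrix metalloproteinase gene MMP7 had 3082 against 6.2 to 397 (4.84 ± 2.18). The epidermal differentiation gene ZNF750, the imprinted gene H19, the cofactor gene VGLL1 and the RNA sensor gene TLR3 differed by 4.44 ± 0.26, 4.26 ± 0.46, 5.56 ± 1.38 and 4.39 ± 1.28. RET, which is rearranged in this line, had a signal of 189 against 4.7 to 33.1. Among the low genes, ECHDC3 had 2.0 against 80.9 to 548, the glycogen phosphorylase gene PYGB had 45.0 against 425 to 1723, and the RNA modification gene QTRT1 had 1.9 against 51.1 to 103.

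Hypoxia and glycolysis genes were lower in LC-2/ad, with a median of -0.77 and 6 of 18 genes at least 2-fold below and 0 above. NDRG1 differed by -2.53 ± 0.91, the pyruvate dehydrogenase kinase gene PDK1 by -2.06 ± 0.88 (-0.95 in its other probe set) and the prolyl hydroxylase gene P4HA1 by -1.77 ± 0.66. Epithelial adhesion and identity genes had a median of 0.94 (8 of 20 above, 0 below), with CLDN3 at 3.41 ± 1.92 and ST14 at 2.80 ± 2.70. Secretory airway markers had a median of 1.2 (4 of 7 above, 1 below) and gastrointestinal markers of 0.66 (5 of 12 above, 1 below), with SLPI at 1.97 ± 1.92 and AGR3 at 3.37 ± 0.87. Alveolar markers had a median of -1.12 (2 of 11 above, 6 below), interferon-stimulated genes of -0.65 (0 of 20 above, 9 below), mesenchymal genes of -0.59 (4 of 21 above, 7 below) and NRF2 targets of -0.36 (3 of 26 above, 6 below). In these lists the vimentin gene VIM differed by -3.94 ± 3.04, while the N-cadherin gene CDH2 was higher at 2.13 ± 0.61. Outside the lists that stood apart, the squalene epoxidase gene SQLE differed by 2.82 ± 1.15 and LEF1 by 2.97 ± 0.58.

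Against the 2 other lines of the brighter set alone, the LC-2/ad medians were -1.0 hypoxia, 2.14 epithelial, 2.71 secretory and -0.92 NRF2, but -0.35 mesenchymal no longer stood apart. Those of 3 lists had the opposite sign (0.94 alveolar, where the median gene was NAPSA, 0.19 interferon and -0.006 gastrointestinal). The hypoxia and epithelial shifts stood apart under every alternative run (the epithelial median 0.60 without A549), whereas without A549 the NRF2 median was 0.28 and the secretory median 0.37, and calls also ended for NRF2 without NCI-H2228 (-0.07), interferon without HCC4006 (-0.01) or NCI-H2228 (-0.48), mesenchymal without NCI-H2009 (-0.10) or NCI-H2228 (-0.26), and gastrointestinal without NCI-H2009 (0.23), HCC4006 (0.48), NCI-H441 (0.42) or NCI-H2228 (0.44). In all, the gastrointestinal call ended under 9 of the 13 alternatives fixed beforehand, the mesenchymal under 5, and the NRF2, interferon and secretory calls under 3 each.

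HCC4006, a line known for an activating EGFR deletion, showed high interferon-stimulated and MHC class II genes and low cell cycle and NRF2 target genes. Its own genes were led by the secretory airway gene SCGB3A1 (chromosome 5, 179949710 to 179951092), with a signal of 5233 in HCC4006 and 1.4 to 2.8 in the other lines, a difference of 9.24 ± 0.11. The matrix Gla protein gene MGP (chromosome 12, 14926094 to 14930035) had 3587 against 0.7 to 17.3 (8.51 ± 0.75, but 2.93 in its other probe set), and the chemokine gene CCL2 had 1386 against 1.3 to 23 (6.46 ± 0.85). TMEM100, HCLS1 and PROM1 differed by 6.83 ± 0.61, 6.55 ± 0.61 and 5.06 ± 0.42. CST4 and CST2, cystatins of similar sequence, differed by 6.89 ± 1.69 and 6.57 ± 1.39. EGFR had a signal of 1964 against 361 to 628, a difference of 1.86 ± 0.33, with 1 of its 9 other probe sets in the opposite direction, and the receptor gene KIT had 591 against 0.8 to 68.2. Low in this line were the ERBB ligand gene EREG (6.3 against 218 to 1618, with a difference of -2.05 in its other probe set), the endoderm transcription factor gene GATA6 (0.9 against 67.9 to 315) and MYC (245 against 1063 to 3996). AKR1C3 differed by -6.46 ± 2.71 and CYP1B1 by -4.32 ± 1.23, the former within a family of near-identical genes.

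Of 20 interferon-stimulated genes, 15 were at least 2-fold above the other lines in HCC4006 and 0 below, with a median of 2.55. IFI27, IFI44L and MX1 differed by 5.85 ± 2.48, 3.95 ± 1.68 and 3.95 ± 1.74. MHC class II presentation had a median of 2.83 (7 of 9 above, 0 below), with CD74 at 4.39 ± 2.93 and HLA-DRA at 4.56 ± 2.74; HLA probe sets can read differently between alleles. Cell cycle genes had a median of -1.51, with 16 of 22 below and 0 above, CCNB1 at -2.14 ± 0.49, TPX2 at -1.88 ± 0.62 and MKI67 at -1.75 ± 0.75 (a median of -0.92 in its 3 other probe sets). NRF2 target genes had a median of -1.73 (1 of 26 above, 18 below), with TXNRD1 at -2.17 ± 0.46 and GCLM at -2.53 ± 0.92. Their mean log2 level of 10.1 in HCC4006 lay near the 10.3 of NCI-H441 and the 10.5 of NCI-H2009. It was 11.3 in LC-2/ad, 13.2 in NCI-H2228 and 13.9 in A549. Alveolar and secretory markers had medians of 1.43 (7 of 11 above, 0 below) and 1.37 (6 of 7 above, 1 below), with NAPSA at 4.09 ± 3.12 and PIGR at 5.48 ± 2.36 (2.39 in its other probe set). MAPK pathway feedback and output had a median of 0.99 (9 of 18 above, 4 below), with SPRY1 at 2.69 ± 1.24. HOX and lineage transcription factors had a median of 1.04 (11 of 19 above, 3 below), with HOXC10 at 4.61 ± 0.88. Epithelial genes had a median of 0.88 (9 of 20 above, 2 below) and hepatic genes of -1.20 (1 of 7 above, 4 below). Inflammatory cytokines and chemokines had a median of -0.60 and a mean of -0.01 (4 of 18 above, 6 below), with PTGS2 at 3.28 ± 1.66. The matrix gene SPARC was higher at 6.07 ± 2.17 and S100A4 lower at -4.51 ± 2.07, both in the mesenchymal list, whose median was -0.14.

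Against the 2 other lines of the dimmer set alone, the HCC4006 medians were 2.04 interferon, 1.76 MHC class II, -1.05 cell cycle, -1.56 NRF2, 1.31 secretory, 0.61 MAPK output, 1.23 HOX, 0.47 epithelial and -1.11 inflammatory, but 0.80 alveolar and -0.08 hepatic, which no longer stood apart. Without A549 the epithelial median was 0.02, the alveolar 0.90 and the hepatic 0.066, the inflammatory call ended without NCI-H2009 (-0.37) or NCI-H2228 (-0.14), and the epithelial median was 1.35 or 1.36 without NCI-H2009 or LC-2/ad. The alternatives fixed beforehand ended the inflammatory call under 5 of 13, the hepatic under 5 of 12, the epithelial under 2 of 13 and the HOX call under 2 of 13 (0.88 without shared probe sets and 1.08 at a minimum signal of 500).

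NCI-H441 showed the highest NKX2-1 signal of the 6 lines together with low mesenchymal, MHC class II and lineage transcription factor genes. NKX2-1 had a signal of 1227 in NCI-H441 and 0.8 to 419 in the other lines. Its difference was 3.33, with a median of 1.78 in its 2 other probe sets. HOPX, an alveolar homeobox gene, had 2859 against 1.8 to 1490, a difference of 5.22 that was 2.25 in its other probe set. VSIG1, a gastric junction gene (chromosome X, 107208381 to 107209072), differed by 6.11 ± 0.76, the glycosyltransferase gene B3GNT6 by 5.89 ± 0.75, the water channel gene AQP4 by 4.31 ± 0.38 and the cornified envelope gene SPRR1B by 4.18 ± 0.35. The iron exporter gene SLC40A1 had 2690 against 104 to 360, a difference of 3.62 that was 1.78 in its other probe set. BEX3 (chromosome X, 102518764 to 102519655) had a signal of 2.8 against 2974 to 6204, a difference of -8.80 ± 0.38. The serine synthesis gene PHGDH had 4.3 against 389 to 1027, the hyaluronan receptor gene CD44 had 18.8 against 678 to 4848, and ANO6, CALD1 and TWF1 differed by -5.56 ± 0.41, -5.82 ± 0.83 and -5.90 ± 0.65, with a far smaller median of -1.88 in the 6 other probe sets of CALD1.

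Alveolar type II markers had a median of 1.76 in NCI-H441, with 7 of 11 at least 2-fold above and 1 below. SFTA3, NAPSA and the surfactant gene SFTPB differed by 4.14 ± 2.51, 4.74 ± 2.93 and 1.76 ± 0.58. Epithelial adhesion and identity genes had a median of 1.31 (13 of 20 above, 0 below), and mesenchymal genes of -1.25 (2 of 21 above, 11 below), with VIM at -5.05 ± 2.68 and the receptor kinase gene AXL at -5.04 ± 1.36 (-2.87 in its other probe set). Basal and squamous markers had a median of 1.36 (4 of 8 above, 0 below), with S100A2 at 3.52 ± 1.64 and IVL at 2.40 ± 0.51. MHC class II presentation had a median of -2.81 (0 of 9 above, 7 below), with HLA-DPA1 at -4.43 ± 2.99 (a median of -2.51 in its 2 other probe sets). HOX and lineage transcription factors had a median of -1.88 (3 of 19 above, 12 below), with PITX1 at -3.89 ± 0.81, FOXA2 at -3.12 ± 1.44 and GATA2 at -2.68 ± 0.33, while FOXA1 was higher at 1.99 ± 0.86. NRF2 targets had a median of -1.09 (1 of 26 above, 13 below), with SRXN1 at -2.56 ± 1.54.

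Against the 2 other lines of the dimmer set alone, the NCI-H441 medians were 1.17 alveolar, 1.30 epithelial, -1.42 mesenchymal, 1.91 basal, -5.47 MHC class II, -1.76 HOX and -0.92 NRF2. Without A549 the epithelial median was 0.58 and without NCI-H2228 the mesenchymal median was -0.76, both still apart, and the basal list with no filter on low signal (0.39) and the mesenchymal list without shared probe sets (-0.95) were not.

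NCI-H2228, a line known for an ALK rearrangement, combined high inflammatory, MHC class II and NRF2 target genes with low epithelial genes. ALK had a signal of 172 in NCI-H2228 and 1.2 to 12.3 in the other lines, a difference of 3.98 ± 0.54 that was 1.78 in its other probe set. The decoy cytokine receptor gene IL13RA2 (chromosome X, 114144802 to 114158431) had 2564 against 0.4 to 33.2 (7.62 ± 1.06) and the complement protease gene C1S had 2566 against 1.4 to 90.5 (7.16 ± 1.46, but 3.80 in its other probe set). The pattern recognition gene PTX3, the microtubule gene MAP2, the anti-angiogenic gene SERPINF1 and the netrin receptor gene UNC5B differed by 6.19 ± 1.16, 5.35 ± 1.52, 4.94 ± 0.49 and 4.84 ± 1.0. ERP44, a chaperone gene of the secretory pathway (chromosome 9, 101784603 to 101901115), had a signal of 12.9 against 459 to 951, a difference of -5.22 that was -1.43 in its other probe set. IL17D, AP1S3, ST3GAL5 and KLHL9 differed by -4.51 ± 0.53, -4.70 ± 0.60, -4.47 ± 0.62 and -4.91 ± 0.92. The receptor gene ERBB3 had 81.8 against 570 to 1217, while KEAP1 had 1135 against 92.5 to 482.

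Inflammatory cytokines and chemokines had a median of 2.26 in NCI-H2228, with 12 of 18 at least 2-fold above and 1 below. CXCL1, CCL20, IL6 and CXCL8 differed by 3.70 ± 1.36, 3.49 ± 0.66, 3.23 ± 0.77 and 2.85 ± 1.11, the last with 0.32 in its other probe set. MHC class II presentation had a median of 3.17 (7 of 9 above, 0 below), with HLA-DQA1 at 4.67 ± 0.21 and HLA-DRB1 at 4.38 ± 2.21. HLA-DQA1 had a signal of 3.6 in HCC4006, although the class II median there was 2.83. As HLA probe sets can read differently between alleles, its difference may not be one of expression. MHC class I had a median of 0.85 (6 of 13 above, 0 below), with TAP1 at 1.63 ± 1.25. NRF2 target genes had a median of 1.69 (16 of 26 above, 0 below), with OSGIN1 at 5.0 ± 0.79, CYP4F11 at 4.76 ± 2.35 and GCLC, which encodes a subunit of the enzyme that starts glutathione synthesis, at 1.72 ± 0.60. Fibroblast markers had a median of 3.44 (4 of 5 above, 1 below) and mesenchymal genes of 0.89 (10 of 21 above, 3 below), with COL6A3 at 3.44 ± 0.39, the collagenase gene MMP1 at 4.35 ± 0.44 and FBN1 at 4.26 ± 0.87. COL1A1 differed by 4.12 ± 1.47 with 1 of its 2 other probe sets in the opposite direction. Epithelial adhesion and identity genes had a median of -1.33 (0 of 20 above, 14 below), with CDH1 at a signal of 342 against 1897 to 4488 and GRHL2 at -2.82 ± 2.14. Cell cycle genes had a median of -0.97 (0 of 22 above, 10 below), with RRM2 at -3.61 ± 1.43 and CDK1 at -2.22 ± 0.76. MAPK pathway feedback and output had a median of 0.89 (8 of 18 above, 2 below), with ETV5 at 2.74 ± 0.62 (a median of 0.46 in its 3 other probe sets). HOX and lineage transcription factors (6 of 19 above, 11 below) and xenobiotic metabolism (1 of 16 above, 7 below) had medians of -1.16 and -0.85. All of these groups were read on the array with the ACTB ratio of 2.46.

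Against the 2 other lines of the dimmer set alone, the NCI-H2228 medians were 2.10 inflammatory, 2.25 MHC class II, 2.12 NRF2, 3.02 fibroblast, 0.89 mesenchymal and -1.87 epithelial, but 0.73 MHC class I, -0.39 cell cycle, 0.24 MAPK output, -0.56 HOX and -0.23 xenobiotic no longer stood apart. The mesenchymal median was -0.99 without shared probe sets (1.58 without HCC4006), the fibroblast median was 0.29 with no filter on low signal, and without A549 the xenobiotic (-0.36), MAPK output (0.37) and MHC class I (0.23) calls ended and the epithelial median was -2.23 (MHC class I 1.30 without NCI-H2009). Of the 13 alternatives fixed beforehand, 3 ended the mesenchymal call (0.43 with a larger pseudocount and 0.30 with the median over probe sets were the others), 2 each the MHC class I and xenobiotic calls and 1 each the MAPK output and HOX calls (HOX -0.34 without shared probe sets). The fibroblast call, with 5 of 11 listed genes measured, ended under 1 of its 11 fixed alternatives. Under the rest of the 13, fewer than 5 members were measured and no call could be made. Among the measured members, MMP1 passed the minimum signal only through NCI-H2228, with 313 against 4.6 to 15.1 elsewhere.

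**Figure D3:**
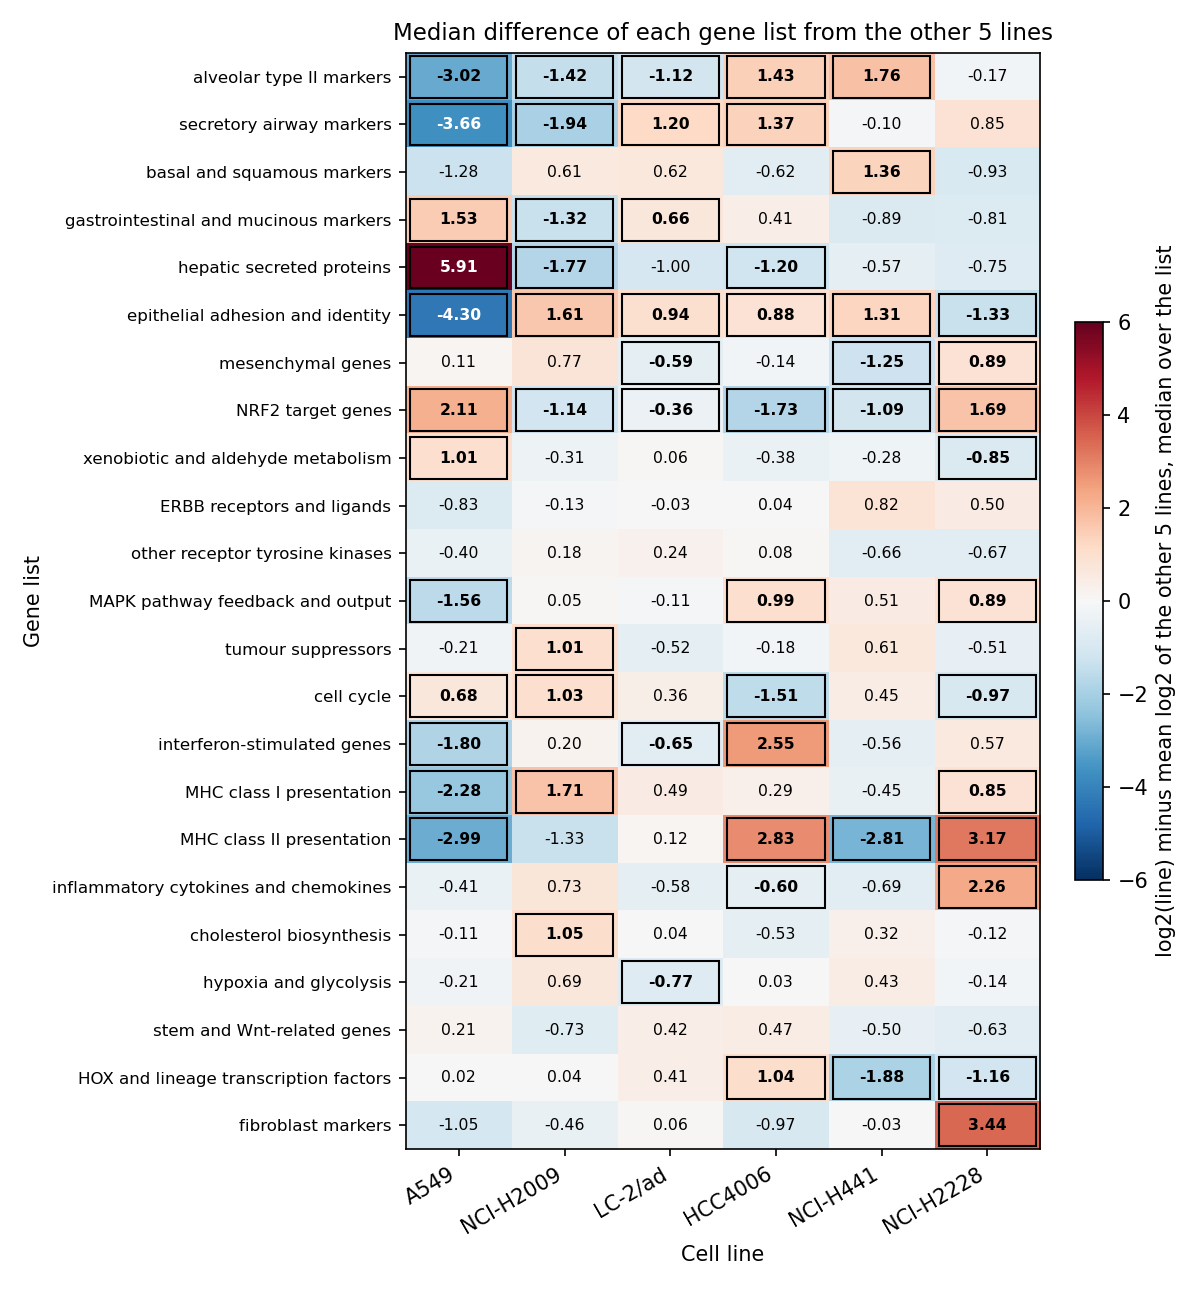
Median difference of each tested gene list (vertical axis) in each cell line (horizontal axis) from the mean of the other 5 lines, on the log2 scale, as colour and number. Boxes mark the 59 values within the lowest or highest 0.5% of 10000 random lists; the highest median is 5.91 for hepatic secreted proteins in A549 and the lowest is -4.30 for epithelial genes in A549.

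**Figure D4:**
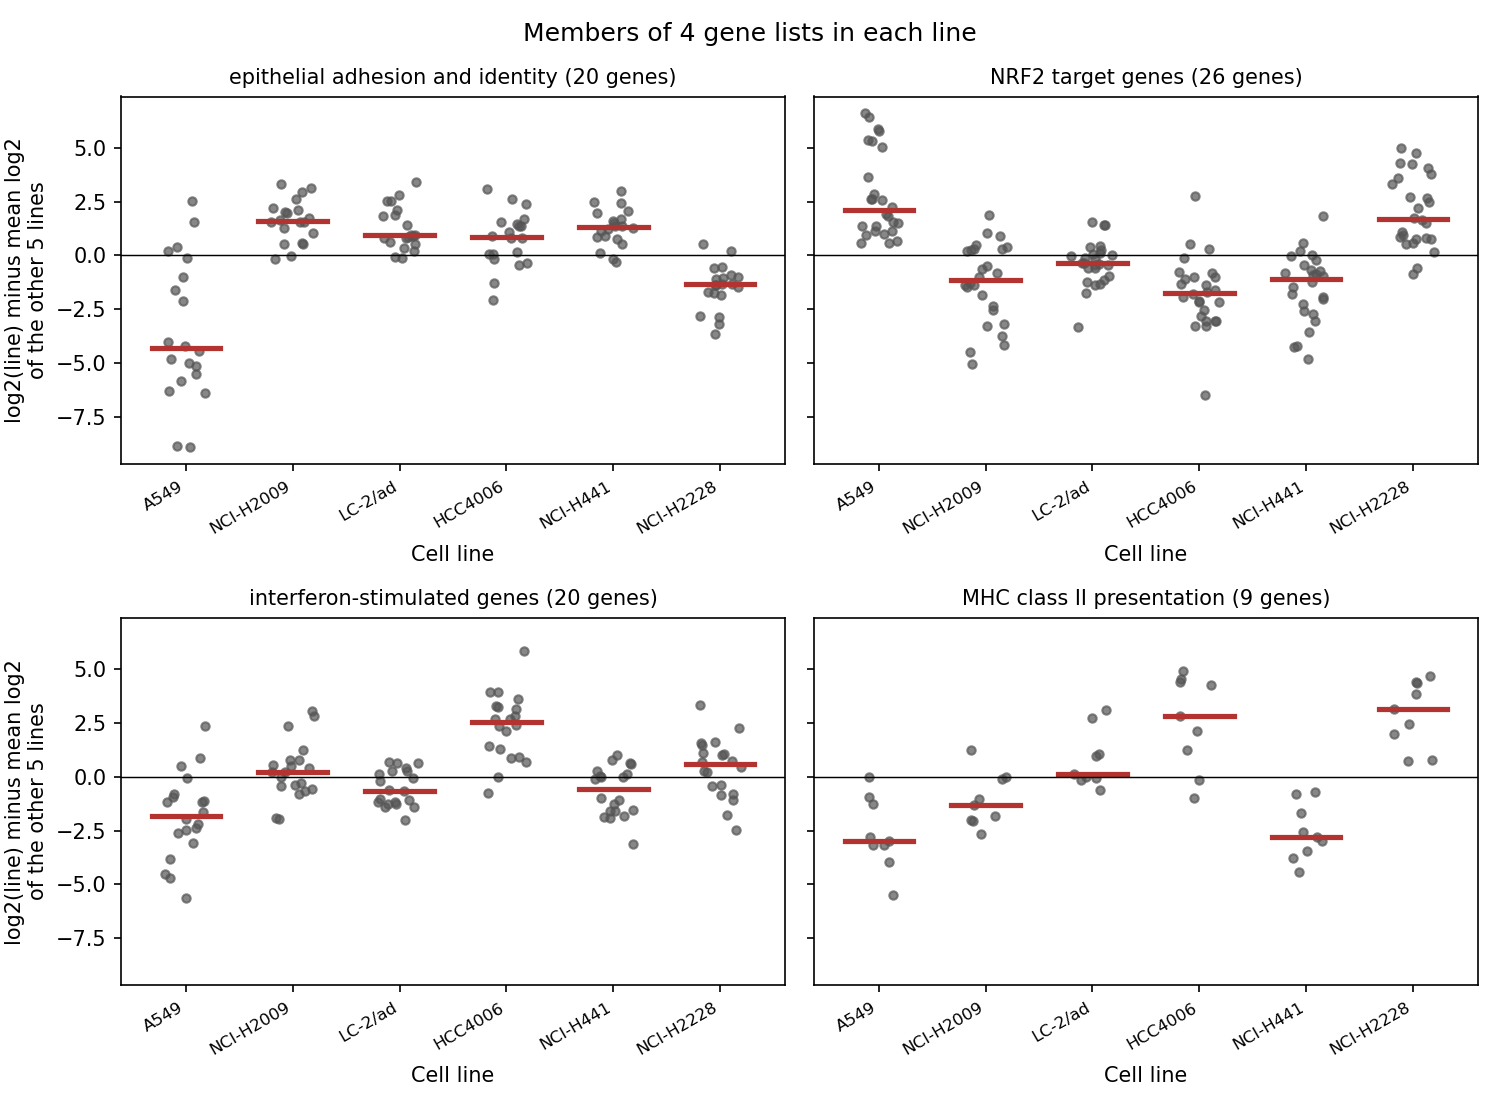
Difference of each measured member (grey points) of 4 gene lists in each line from the mean of the other 5 lines, on the log2 scale, with the median as a red bar. NRF2 target genes have medians of 2.11 in A549 and 1.69 in NCI-H2228, and MHC class II genes of 2.83 in HCC4006 and 3.17 in NCI-H2228.

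Seen across the lines, NRF2 target genes were highest in A549 and NCI-H2228, and MHC class II genes in HCC4006 and NCI-H2228, while epithelial genes were lowest in A549 and NCI-H2228. The mean log2 level of NRF2 targets was 13.9 in A549, 13.2 in NCI-H2228 and 10.1 to 11.3 in the other lines. The lower NRF2 medians of those other lines therefore partly reflect A549 and NCI-H2228 in their reference. The mean log2 level of epithelial genes was 8.4 in A549, 10.1 in NCI-H2228 and 11.9 to 12.6 in the other lines. The higher epithelial medians of those other lines likewise partly reflect A549 and NCI-H2228. Cell cycle levels were lowest in HCC4006 (10.2) and NCI-H2228 (10.5), against 11.7 to 12.1 elsewhere. Some lists fixed beforehand set no line apart: ERBB receptors and ligands had medians from -0.83 in A549 to 0.82 in NCI-H441, other receptor tyrosine kinases from -0.67 in NCI-H2228 to 0.24 in LC-2/ad, and stem and Wnt-related genes from -0.73 in NCI-H2009 to 0.47 in HCC4006. Single members still differed, with NRG1 at 4.70 ± 1.09 and DKK1 at 4.0 ± 1.24 in A549, BTC at 2.08 ± 1.16 in NCI-H441 and EPHA2 at 1.63 ± 0.47 in NCI-H2009. Too few members for a median were measured of ciliated cell markers (2), neuroendocrine markers (3), cancer-testis antigens (4), endothelial markers (4) and haematopoietic markers (2).

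LC-2/ad and NCI-H441 were the most alike, with a Pearson correlation of 0.868 across genes and 791 genes at least 4-fold apart, and NCI-H2009 and HCC4006 the least, with 0.687 and 2425 genes. The mean correlation with the other 5 lines was 0.809 for LC-2/ad and 0.724 for NCI-H2009. Genes are not independent replicates, so these values carry no test. The 6 pairs from the same array set had correlations of 0.694 to 0.806 (median 0.775) and the 9 pairs from different sets 0.687 to 0.868 (median 0.744). With no filter on low signal, both correlations were higher, at 0.923 and 0.838.

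Of 4 relations between gene groups fixed beforehand, tested over the 6 lines with two-sided exact permutation tests, none reached an adjusted p of 0.05. NKX2-1 and the 10 other alveolar markers had Pearson r = 0.703 (exact p = 0.103, adjusted 0.252) and Spearman rho = 0.486 (exact p = 0.356, adjusted 0.474). Without A549 and NCI-H441 r was -0.22, so the relation was not seen in the remaining 4 lines. Leaving out the lines farthest from the median narrows the range of NKX2-1 by construction, which alone can lower r. It was 0.328 without A549 alone and 0.583 without NCI-H441 alone. MAPK output and 4 measured ERBB ligand genes had r = 0.634 (exact p = 0.160, adjusted 0.252) and rho = 0.543 (exact p = 0.297, adjusted 0.474). Without A549 and NCI-H2228 that r was -0.55, and it was -0.009 without A549 alone and 0.948 without HCC4006. Interferon-stimulated and MHC class I genes had r = 0.620 (exact p = 0.189, adjusted 0.252) and rho = 0.60 (exact p = 0.242, adjusted 0.474), with 0.871 left without A549 and HCC4006 and 0.965 without HCC4006 alone. Epithelial and mesenchymal genes had r = -0.18 (exact p = 0.715, adjusted 0.715) and rho = -0.20 (exact p = 0.714, adjusted 0.714), 0.085 without A549 and NCI-H2228, 0.104 without NCI-H441 and 0.051 without NCI-H2228. With each value less the mean of its array set, and all 36 pairings within the sets, none reached an adjusted p of 0.05 either. The set-adjusted r was 0.835 for NKX2-1 with the alveolar markers (exact p = 0.111, adjusted 0.333) and 0.517 for MAPK output with ERBB ligands (exact p = 0.278, adjusted 0.370). It was 0.648 for interferon-stimulated with MHC class I genes (exact p = 0.167, adjusted 0.333) and -0.173 for epithelial with mesenchymal genes (exact p = 0.583, adjusted 0.583). The set-adjusted rho was 0.429, 0.257, 0.543 and -0.143 in the same order. Its exact p values were 0.472, 0.611, 0.306 and 0.833 (adjusted 0.815, 0.815, 0.815 and 0.833). A single set of 3 lines has too few for a correlation of its own.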

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

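The tests of RNA degradation and of the choice of probe set in NCI-H2009 and of RNA mixed into LC-2/ad, and the division of the latter into separate tests for NCI-H441 and for the other 4 lines, were chosen after the result was seen. Of 28 measures screened for a line far from the other 5, where chance gives about 1.4, 5 had such a line. The mean log2 level of hepatic secreted proteins was 10.9 in A549 and 6.92 to 7.38 in the other lines. The filter on low signal favoured this difference, as 7 of the 15 listed genes were measured. Among them, FGA and FGG passed the minimum only through A549, with signals of 2.5 to 7.6 and 0.8 to 21.3 elsewhere. With no filter on low signal, the hepatic shift in A549 no longer stood apart. The mean level of MAPK pathway feedback and output genes was 9.35 in A549 and 10.5 to 11.2 elsewhere. The mean level of hypoxia and glycolysis genes was 9.83 in LC-2/ad and 10.5 to 10.9 elsewhere. The other 2 were control transcripts on the NCI-H2228 array, whose 3' to 5' ratios were 2.46 for ACTB (1.06 to 1.27 on the other arrays) and 1.25 for GAPDH (0.907 to 1.02).

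The NCI-H2228 array had the highest 3' to 5' ratio of both control transcripts reported, a pattern that shortened RNA or incomplete labelling gives. Its differences also varied most between probe sets of the same gene, with an SD of 0.893 against 0.489 to 0.759 on the other arrays, so shortened RNA may have disturbed single gene values, although NCI-H2009, with the lowest ACTB ratio, had the next highest SD. Shortened RNA as the source of its 38 low genes cannot be told apart from low expression: in the 27 with other probe sets the median difference there was -1.77, but shortened RNA lowers any probe set away from the 3' end, so that test, although planned, decides nothing. With the median over probe sets 55 genes were low in this line, 21 of them among the 38. No biological explanation of the ratios was tested.

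NCI-H2009 had 279 genes at least 4-fold below every other line, against 162 in the next line. Degraded RNA was argued against by its ACTB ratio of 1.06, below the 1.11 to 2.46 of the other arrays. Faults of single probe sets as the source of the low values were argued against by a median difference of -1.86 in the other probe sets of these genes, with 168 of 203 at least 2-fold lower, but the size of the count and the lead over the next line rested on the choice of probe set: with the median over the probe sets of a gene 101 genes were low, 78 of them among the 279, against 91 in A549. Scaling and brightness also stay open as part of the pattern, since after quantile normalization the count was 215 (211 of the 279 among them) and other lines had 12 to 172, so the lead could be partly a matter of array brightness. A property of the cell line itself stays open and untested, as each line has 1 array.

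LC-2/ad had the fewest genes set apart in total, 25 above and 12 below. A compressed signal range of its array was argued against by an SD over genes of 2.01, within the 1.89 to 2.16 of the other arrays. RNA of another line mixed into the sample would bring all the abundant transcripts of that line. A share under 10% would be too small to bring genes within 4-fold of that line's own level. It could still lift a gene that is much higher in that line than in the lowest line, and so hide a low gene. A mixture of under 10% was not tested. Of the genes with a signal of at least 500 that set a line apart from the remaining lines, those under 10% of its signal in LC-2/ad were 58 of 76 for A549, 17 of 37 for NCI-H2009, 29 of 50 for HCC4006, 31 of 39 for NCI-H2228 and 4 of 16 for NCI-H441 (at 1.11% to 6.36%). This argues against a mixture of 10% or more with any of the 5, but for NCI-H441 it rests on those 4 genes. The limit of 500 was set after the values were seen. Without it, the genes reaching 10% were 30 of 42 for NCI-H441 (median share 24.0%), 64 of 118 for NCI-H2009 and 78 of 156 for HCC4006. They were 51 of 189 for A549 and 29 of 88 for NCI-H2228. A likeness of LC-2/ad to the other lines, such as NCI-H441 with the highest correlation of any pair at 0.868, stays open and untested with 1 array per line.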

How the results depend on the processing

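The comparison within array sets and the relations adjusted for the array set were the alternatives chosen after the controls were seen, and their tests are named here as such. No paired analysis was possible because each line has 1 array and no comparison comes from a fit with replicates. The deposited tables hold the same values and each array was scaled by the same factor, so the alternatives that use the deposited scale or the other table change nothing and were not run separately. The number of genes compared was 12769, and 12747 with the smaller and 12791 with the larger pseudocount, 19674 with no filter, 10395 at a minimum of 500, 12851 after quantile normalization, 12811 with the 75th percentile, 10617 with the median over probe sets and 9659 without shared probe sets.

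The number of list shifts that stood apart was 59, and 51 to 65 under the settings with all 6 lines and 47 to 57 when 1 line was left out, which also leaves fewer combinations. Of the 59 shifts, 29 kept their direction and their side of the threshold under the alternatives fixed beforehand, which numbered 13 for most shifts and 11 or 12 for 5. Within the array set, 43 of the 59 kept both, 11 kept only the direction and 5 had the opposite sign, and 26 kept both there and under all of the others. The 26 include NRF2 targets in A549, NCI-H2009, HCC4006, NCI-H441 and NCI-H2228 and epithelial genes in every line but HCC4006. They also include MHC class II genes in A549, HCC4006, NCI-H441 and NCI-H2228. A549 and NCI-H2228 had the highest NRF2 and the lowest epithelial levels. Every alternative kept at least 1 of them in the reference of the remaining lines. The NRF2 and epithelial shifts of those remaining lines were therefore not tested apart from A549 and NCI-H2228. Over all alternatives, recomputed shifts kept direction and side of the threshold in 713 cases, no longer stood apart in 98 and had the opposite sign in 9. The 9 were, with no filter, hepatic genes in NCI-H2009 (0.229), without shared probe sets, mesenchymal genes in NCI-H2228 (-0.989), without A549, NRF2 targets in LC-2/ad (0.278, lowest value -0.729 without HCC4006) and hepatic genes in HCC4006 (0.066, lowest value -1.751 without NCI-H2009), and within the array set, cell cycle in A549 (-0.009), alveolar markers in NCI-H2009 (0.565) and LC-2/ad (0.938), and gastrointestinal (-0.006) and interferon genes (0.191) in LC-2/ad. Values of single genes moved by less than the SD of the other lines in 2911 cases, by more in 250 and to the opposite sign in 3. CDH1 in A549 had the opposite sign without NCI-H2228 (-0.39, highest value 0.532 without NCI-H2009) and within the array set (-0.569), as had NAPSA in LC-2/ad within the array set (0.938). Apart from leaving out lines, which changes the reference, the cause was not tested.

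Counts of genes set apart moved by over 1.5 times as follows. With the smaller pseudocount, genes below were 254 in A549, 33 in LC-2/ad, 17 in HCC4006, 161 in NCI-H441 and 80 in NCI-H2228. With the larger one, genes above were 44 in NCI-H2009, 16 in LC-2/ad, 75 in HCC4006 and 11 in NCI-H441, and genes below were 73 in A549, 103 in NCI-H2009, 1 in LC-2/ad, 6 in HCC4006, 28 in NCI-H441 and 19 in NCI-H2228; a larger pseudocount shrinks differences from low signals. With the median over probe sets, genes below were 91 in A549, 101 in NCI-H2009, 3 in HCC4006 and 35 in NCI-H441, and genes above 47 in NCI-H2228. Without shared probe sets, genes below were 105 in A549, 7 in LC-2/ad and 6 in HCC4006; the cause was not tested for these settings. Against the median of the other lines, a less strict measure, genes above and below were 481 and 683 in A549, 529 and 1039 in NCI-H2009, 252 and 211 in LC-2/ad, 575 and 203 in HCC4006, 264 and 467 in NCI-H441 and 539 and 447 in NCI-H2228. Scaling to the 75th percentile moved the share of genes above among those set apart in NCI-H2009 from 22.9% to 33.8%, and moved the median difference of all genes from 0.14 to 0.30 in NCI-H2009 and from 0.007 to -0.18 in HCC4006.

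Leaving out 1 line removes a competitor and so can only raise these counts for a fixed set of genes. Genes above ranged from 176 to 205 in A549, 108 to 121 in NCI-H2009, 30 to 41 in LC-2/ad, 131 to 161 in HCC4006, 28 to 42 in NCI-H441 and 88 to 144 in NCI-H2228, and genes below from 177 to 237, 306 to 387, 16 to 33, 14 to 30, 103 to 121 and 46 to 88 in the same order. Moves over 1.5 times for genes above were LC-2/ad without HCC4006 (41) or NCI-H441 (38), NCI-H441 without NCI-H2009 (36), LC-2/ad (42) or HCC4006 (40), and NCI-H2228 without A549 (120), NCI-H2009 (133) or HCC4006 (144). For genes below they were LC-2/ad without A549 (33), NCI-H2009 (24) or NCI-H441 (30), HCC4006 without A549 (17), LC-2/ad (16), NCI-H441 (25) or NCI-H2228 (30), and NCI-H2228 without A549 (88), NCI-H2009 (65) or HCC4006 (73).

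The relations ranged, over 5 lines each, from 0.328 to 0.866 for NKX2-1 and alveolar markers, -0.009 (without A549) to 0.948 (without HCC4006) for MAPK output and ERBB ligands, 0.166 to 0.965 (without HCC4006) for interferon and MHC class I genes, and -0.562 to 0.104 (without NCI-H441, with 0.051 without NCI-H2228) for epithelial and mesenchymal genes. The 2 values without HCC4006 passed an unadjusted exact permutation threshold of 0.05, and the cause was not tested. Adjusted for the array set, the 4 relations kept their sign and none passed that threshold. With no filter, the correlation across genes was 0.923 for LC-2/ad and NCI-H441 and 0.838 for NCI-H2009 and HCC4006, where genes low on both arrays enter by construction. Signal over background limits the low genes most, as their counts moved with the pseudocount.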

Other observations

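The test of neighbouring genes was chosen after the low genes were seen. Some genes of the fixed lists differed between groups of lines, without being special to 1 of them, and their signals in deposited units were as follows. MTAP, a methionine salvage gene beside CDKN2A on chromosome 9 (21792634 to 22022985), had a signal of 0.6 in HCC4006 and 0.6 in NCI-H2228, 11.7 in LC-2/ad, 51.3 in NCI-H441, 66.8 in A549 and 156 in NCI-H2009. In A549 the 3 other probe sets of MTAP pointed the opposite way, with a median difference from the other lines of -1.58 against 1.60, so its level there is uncertain, and their median was -0.87 in HCC4006 and -1.45 in NCI-H2228 against -2.47 in both. CDKN2A itself, which was set apart in NCI-H2009, had 4811 there, 538 in NCI-H441 and 9.2 to 33.2 in the other 4 lines. The receptor kinase gene MET had 5320 in LC-2/ad and 4957 in NCI-H441, and 1301 to 1931 in the other lines, with a median difference in HCC4006 of 0.27 in other probe sets against -0.52. The transcription factor gene SOX2 had 2.4 in A549 and 15.5 in NCI-H2228, and 280 to 892 in the other lines, and its difference in A549 was -4.91 but -2.03 in other probe sets. The ubiquitin hydrolase gene UCHL1, a neuroendocrine marker, had 5582 in A549 and 3922 in NCI-H2228, and 5.8 to 639 in the other lines, with differences in its other probe set of -1.82 against 1.02 in NCI-H2009 and 2.03 against 4.76 in A549.

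The cancer-testis antigen genes MAGEA3 and MAGEA6, which are nearly identical in sequence, had signals of 495 to 1289 in A549, NCI-H2009 and LC-2/ad and of 0.8 to 7.0 in HCC4006, NCI-H441 and NCI-H2228. This division coincides with the brighter and dimmer array sets, whose spike-in signals differed by mean ratios of 2.22 to 3.13 and whose 18S ribosomal RNA signals were 328 to 1272 and 33.6 to 67.8. PRAME, another member of the list, had 642 in A549, 413 in NCI-H2009 and 141 in HCC4006, and 8.9 to 23.5 in the other lines. Division of the 6 arrays by spike-in brightness gave 78 genes at least 2-fold apart between all lines of the sets, and the other divisions into 3 and 3 gave 31 to 137 (median 56). Of the 10 divisions, 5 gave at least as many genes, this one included, and 10 are too few for a share under 0.05.

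A hypothesis was that genes low in 1 line lie side by side on a chromosome, as the loss or silencing of a segment would leave them. In NCI-H2009, 18 pairs of low genes were direct neighbours among the genes compared, against a mean of 6.12 and a highest value of 17 over 10000 random placings. Segments lost or silenced in that line could leave such pairs, but neighbours with shared regulation or similar sequence would give the same count. With the median over probe sets, only 78 of the 279 low genes stayed low. The placings were not repeated on those genes. Groups of 3 low genes with at most 1 other compared gene between each and the next were chosen after their values were seen. They included MYNN, SEC62 and PHC3 on chromosome 3 (170973896 to 171290099) and LTN1, USP16 and BACH1 on chromosome 21 (29222336 to 29640177). Each of these groups spanned 5 compared genes, so its members were not direct neighbours and it adds no pair to the 18. The only group of NCI-H2009 made up of direct neighbours was SMA3, GUSBP16 and an uncharacterised locus on chromosome 5 (69184598 to 69321690). The pairs numbered 8 in A549 (random mean 2.06, highest 10), among them the similar IFITM1, IFITM2 and IFITM3, and 4 in NCI-H441 (random mean 0.558, highest 5), among them BEX2, TCEAL9 and BEX3 on chromosome X (102450930 to 102519655). NCI-H2228, LC-2/ad and HCC4006 had 0. Genes high in A549 also lay side by side, with 10 pairs (random mean 2.09, highest 9) that include FGB, FGA and FGG on chromosome 4 (155703612 to 155753253), a cluster known to be regulated together. High genes of HCC4006 formed 5 pairs (random mean 0.978, highest 6), among them CST4, CST1 and CST2 of similar sequence, and those of NCI-H2009 formed 3 (random mean 0.50, highest 5).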
